A study of Mus musculus with 6 samples.

How the data were processed

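The series holds poly-A RNA sequencing of mouse subcutaneous white adipose tissue in 6 libraries, 3 titled WT and 3 titled Tumor, with biological replicate numbers 1 to 3 in each group, and each library carries its own identifier in the description label. Per the labels' protocols, RNA had an integrity number above 7, libraries were made with TruSeq chemistry and KAPA HiFi for the last amplification, and the design text names an Element AVITI sequencer. Per the submitters' processing notes the genome build was GRCm38.p6 and DESeq2 was among the tools, with no version and no role given. The aligner, the quantification tool and the annotation release are not given in the sources used here. The identifiers of the 2 groups come from number ranges far apart, so a batch that follows the groups cannot be told apart from them.

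The authors deposited 1 table for the series, named as raw counts, but its values are TPM, shares of transcripts corrected for transcript length, as the values themselves show. Each column sums to 1000000 and the values are not whole. For genes with a single transcript over 1 kb, the TPM multiplied by the transcript length less 160 to 170 nt fell on multiples of a fixed step in each library, and 77.6% to 79.9% of low values lay within 0.15 of a whole multiple. These steps depend on the length used for each gene, so counts were not rebuilt and library totals are not known. TPM are shares of a total, so that a rise of abundant lymphoid or muscle transcripts lowers all others. The table has 36144 gene rows with gene symbols and no identifiers. Of these names 26 are spreadsheet dates and cannot be traced to a gene, and 2 names stand on more than 1 row. Symbols were matched to GENCODE M21 on GRCm38 for coordinates, and 35859 matched a single gene. Reads shared with pseudogenes or close paralogs were divided by a rule not given in the sources used here, and values of such genes are uncertain.

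The tests fixed before the data were examined assumed counts. Because the table holds TPM, the main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend and robust variance moderation, in a model with group alone. The genes tested were the 14144 with at least 1 TPM in at least 3 libraries, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Differences are on the log2(TPM + 1) scale and understate changes of low genes. Adjusted p-values of genes in the text are from limma. The 40 gene lists were fixed before the data were examined, and the 37 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. An exact permutation test of 3 against 3 libraries cannot go below 0.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

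The rule for the named genes, fixed before the data were examined, took Msra, then up to 12 genes per direction with the largest differences among genes past the threshold, with a mean of at least 5 and no overlap between the groups, and from each list up to 4 members past the threshold or, where none passed, the 2 with the smallest p, given as values. Its minimum of 5 was set for counts per fixed total and was applied to TPM. No gene passed, so that Msra and up to 2 members per list are named. Some genes that the rule takes are not reported here. Members of the thermogenic and sex lists could be given as values too, which is how Ucp1 is named. Cd79a, Glycam1, Acta1 and Adipoq were named after their values were seen.

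The procedure was tested on simulated data built from the 14144 real genes and their means, with 200 genes changed. The 200 were drawn from genes at higher levels only, and changes were added on the log2(TPM + 1) scale. Recovery of changes in low genes was therefore not measured. With the residual spread observed for each gene, 10% of 2-fold and 51.2% of 4-fold changes were recovered, with 3.2 false calls on average over 5 draws. With the spread set to the lower quartile over genes, 97.4% and 100% were recovered, with 8.2 false calls on average. A list shifted by 1 on the log2 scale was found in all 5 draws, with simulated errors that were independent between genes.

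Alternatives fixed before the data were examined were leaving out each library, the replicate number as a block, a minimum log2 difference of 1, and the estimated correlation and fry for lists. A fit without robust moderation, median-ratio and upper-quartile factors, no filter on low values and a stricter filter were fixed for a count test and were carried over to TPM, the last as at least 5 TPM in 3 libraries. Pseudocounts of 0.1 and 0.5, limma without the trend, cell type lists and the first principal component as covariates, and a fit of the 4 lymphoid-rich libraries were chosen after seeing the data. With the B and plasma cell covariate each of the 6 libraries was also left out in turn and the lists were tested with an estimated correlation, again choices made after seeing the data.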

Results

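RNA sequencing of mouse subcutaneous white adipose tissue, the fat depot under the skin, was examined in 6 libraries, 3 titled WT and 3 titled Tumor. The labels describe the same 3 against 3 libraries in different ways. The sample titles contrast WT with Tumor, the genotype label calls these sets wild type and full-body knockout for Msra, and all 6 carry the same treatment label, an orthotopic transplant. The design text speaks of pancreatic ductal adenocarcinoma cells transplanted into wild-type and Msra knockout hosts and of tissue taken 4 to 5 weeks after surgery, whereas the series title speaks of tumour-bearing mice and tumour-free controls. The comparison is therefore given as libraries labelled Tumor against libraries labelled WT. Each deposited column summed to 1000000 in TPM, a share of all transcripts corrected for transcript length, so the total number of reads per library is not known. A single fragment was worth 0.0384 to 0.0510 TPM and 3 fragments 0.115 to 0.153 TPM. This holds where the transcript length less 160 to 170 nt is 1 kb. The floor covers counting error only and is higher for shorter transcripts. The libraries listed 13077 to 14253 genes at 1 TPM or more.

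Msra encodes methionine sulfoxide reductase A, which reduces oxidised methionine in proteins, and lies on chromosome 14 from 64122625 to 64455903 (GRCm38, GENCODE M21). It was measured in every library. Msra stood at 51.1, 59.1 and 56.3 TPM in the libraries labelled WT and at 52.9, 40.0 and 26.9 TPM in those labelled Tumor, which the genotype label calls knockout. These last 3 values were 95.4%, 72.1% and 48.4% of the mean of the libraries labelled WT. The group means were 55.5 ± 4.05 and 39.9 ± 13.0 TPM (SD, n = 3), and the log2 difference of -0.51 (SE 0.26, limma adjusted p = 0.737) did not pass the test. It was -0.26 without Tumor replicate 3, -0.33 with the adipocyte identity list as a covariate and -0.89 with the macrophage list as a covariate. Values summed over a whole gene do not show whether an exon is missing. Since Msra was not lost where the genotype label says knockout, every direction below is drawn from the title labels.

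The libraries differed most in lymphoid transcripts, and this difference crossed the groups. Cd79a, part of the B cell receptor, stood at 277, 235 and 0.775 TPM in the libraries labelled WT and at 1.71, 449 and 712 TPM in those labelled Tumor. Glycam1, a product of lymph node high endothelial venules, followed the same division, with 385, 344 and 0.319 TPM against 1.23, 363 and 788 TPM. WT replicate 3 and Tumor replicate 1 were thus poor in lymphoid transcripts and the other 4 libraries rich. The first principal component held 70.7% of the variance and placed these 2 libraries at 92.5 and 76.0 and the other 4 between -80.7 and -24.5. Skeletal muscle transcripts also varied, with Acta1 (skeletal muscle actin) at 0.953, 612 and 2.82 TPM against 410, 135 and 575 TPM. The adipocyte hormone Adipoq stood at 1413, 1711 and 3403 TPM against 3455, 2023 and 721 TPM. Transcripts of the mitochondrial genome took 14.7%, 14.9% and 18.6% of the TPM in the libraries labelled WT and 13.2%, 12.3% and 8.52% in those labelled Tumor.

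No single gene passed the test between the groups. Of 14144 genes tested with limma, 0 had an adjusted p below 0.05, and the smallest adjusted p was 0.206. At an unadjusted p below 0.05 there were 771 genes, 530 higher and 241 lower in the libraries labelled Tumor, where 707 would be expected by chance. The median log2 difference of all genes was 0.23. Median-ratio factors brought that median to 0.04 and turned the unadjusted division to 129 higher and 522 lower, and upper-quartile factors gave 0.06 with 157 higher and 441 lower, so the direction of single genes near the median depends on the scaling. Every library labelled Tumor lay above or below every library labelled WT for 2126 genes (15.03%, against 10% by chance), 1668 of them higher and 458 lower. Other divisions of the 6 libraries into 3 and 3 separated 271 to 4429 genes in this way, so this count does not set the labelled groups apart. The separation was counted on TPM without scaling factors, so its excess of higher genes may rest on the scaling too. Lists of genes were compared with limma's camera test, and 22 of 37 lists passed at the preset correlation, 20 of them lower and 2 higher. With a correlation estimated from the data 1 list passed, glycolysis. Its estimate was 0.0018, against 0.78 for oxidative phosphorylation and 0.7 for lipogenesis. The same list was the 1 that passed limma's fry test in its directional form, the form used elsewhere here. In the form that ignores direction, glycolysis, interferon response and lipogenesis passed (fry adjusted p = 0.00115, 0.0193 and 0.0498). With the B and plasma cell list as a covariate 0 lists passed at an estimated correlation, glycolysis included (adjusted p = 0.222). Other divisions of the same 6 libraries into 3 and 3 gave 14 to 30 lists past the preset threshold, so that count does not set the labelled groups apart.

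Genes of de novo lipogenesis, the making of fatty acids from sugar carbon, were lower in the libraries labelled Tumor. Elovl6, which elongates palmitate (chromosome 3, 129532355 to 129638495), averaged 74.5 ± 18.7 TPM (SD, n = 3) in the libraries labelled WT and 14.7 ± 1.54 TPM in those labelled Tumor, 5.07-fold lower, with a log2 difference of -2.24 (SE 0.23, limma adjusted p = 0.387). Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), averaged 3697 ± 576 and 999 ± 231 TPM, 3.70-fold lower, with a log2 difference of -1.90 (SE 0.29, limma adjusted p = 0.737). As a list, lipogenesis fell, with a median log2 difference of -1.11 over 19 tested genes (camera adjusted p = 3.13e-27, adjusted p = 0.208 with an estimated correlation). Across the other scalings, filters and covariates this median ran from -1.74 to -0.76. Of its members 17 had a negative difference and 11 were lower in all 3 libraries labelled Tumor than in all 3 labelled WT. Adjusted over all genes 0 members passed, and adjusted over the list alone 10 did. Such counts take no account of the number of lists. Over all lists 41 members passed when adjusted over the list alone, and other divisions of the 6 libraries gave 0 to 80.

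**Figure D1:**
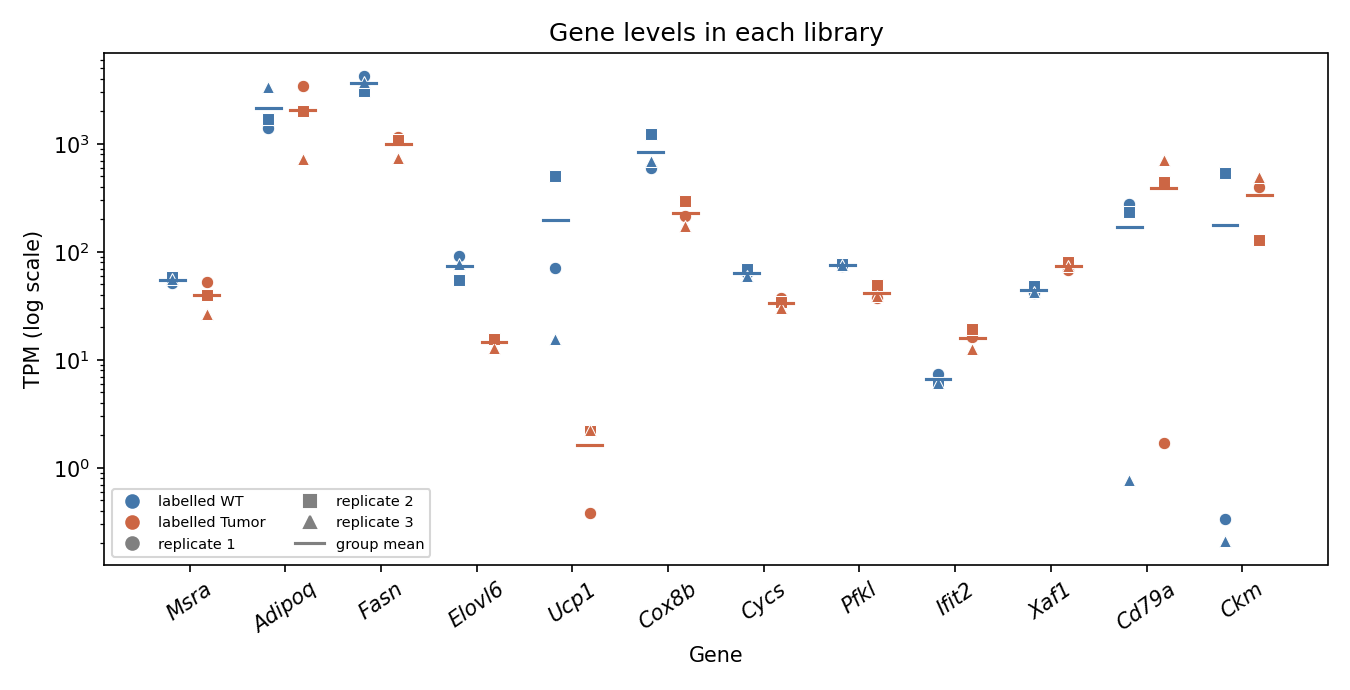
TPM of 12 genes in each of the 6 libraries on a log axis, blue for the 3 libraries labelled WT and orange for the 3 labelled Tumor, with the shape giving the replicate and a line at each group mean. Fasn and Elovl6 are lower and Ifit2 and Xaf1 higher in all 3 libraries labelled Tumor, while Cd79a is near 1 TPM in 1 library of each group.

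Mitochondrial energy genes were lower in the same libraries. All 36 tested nuclear genes of oxidative phosphorylation had a negative difference, and 35 of them separated the groups completely. Cycs, which encodes cytochrome c, averaged 64.4 ± 5.00 and 33.9 ± 3.35 TPM (SD, n = 3), and Uqcrfs1, the Rieske protein of complex III, 252 ± 23.6 and 148 ± 24.6 TPM. This list fell by a median of 0.54 on the log2 scale (camera adjusted p = 1.18e-45, adjusted p = 0.208 with an estimated correlation), and adjusted over the list alone 1 member passed. The tricarboxylic acid cycle list, with pyruvate dehydrogenase, fell by a median of 0.65 over 18 genes, all negative (camera adjusted p = 1.84e-26, adjusted p = 0.208 with an estimated correlation), and 6 members passed over the list alone. Pdhb and Dlat, subunits of pyruvate dehydrogenase, averaged 388 ± 35.1 against 185 ± 22.2 TPM and 105 ± 8.38 against 55.1 ± 14.4 TPM. Fatty acid oxidation fell by a median of 0.78 over 22 genes (camera adjusted p = 5.35e-19, adjusted p = 0.277 with an estimated correlation), with 0 members past over the list alone. Hadha, of the trifunctional protein, averaged 259 ± 40.2 against 148 ± 15.3 TPM and the carnitine carrier Slc25a20 81.0 ± 18.6 against 40.8 ± 9.42 TPM. The 13 transcripts of the mitochondrial genome fell by a median of 0.51 (camera adjusted p = 3.05e-13, adjusted p = 0.277 with an estimated correlation), with 0 past over the list alone. For mt-Nd1 the means were 9728 and 6141 TPM and for mt-Nd3 3818 and 2485 TPM. Without Tumor replicate 3, which had the least Adipoq, the medians of fatty acid oxidation and of the mitochondrial genome were -0.43 and -0.33, and across the other scalings, filters and covariates that of fatty acid oxidation ran from -1.09 to -0.48.

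Thermogenic genes, typical of brown and beige adipocytes, fell as a list by a median of 0.56 over 17 genes (camera adjusted p = 4.45e-13, adjusted p = 0.208 with an estimated correlation). Ucp1, the uncoupling protein that releases mitochondrial energy as heat (chromosome 8, 83290352 to 83298452), stood at 71.1, 507 and 15.7 TPM in the libraries labelled WT and at 0.383, 2.21 and 2.27 TPM in those labelled Tumor. Otop1 averaged 14.7 ± 2.95 and 3.39 ± 1.18 TPM (SD, n = 3), and Cox8b, a cytochrome c oxidase subunit, 839 ± 345 and 227 ± 62.8 TPM. Adjusted over the list alone 7 members passed, all lower. WT replicate 2 held most Ucp1, and the list median ran from -0.82 to -0.52 when each library was left out in turn. It was -1.56 over genes of at least 5 TPM in 3 libraries and -0.91 with the macrophage list as a covariate.

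Glycolysis fell by a median of 0.52 over 17 genes (camera adjusted p = 4.42e-14, adjusted p = 0.0426 with an estimated correlation, fry adjusted p = 0.0287). Pfkl, the liver-type phosphofructokinase (chromosome 10), averaged 75.4 ± 1.93 and 42.1 ± 6.38 TPM, and Eno1, enolase, 778 ± 76.4 and 405 ± 39.8 TPM (SD, n = 3). Adjusted over the list alone 2 members passed. Cholesterol biosynthesis fell by a median of 0.45 over 20 genes (camera adjusted p = 2.74e-10, adjusted p = 0.354 with an estimated correlation), with 1 member past over the list alone. Without WT replicate 3 that median was -0.24, and with the skeletal muscle list as a covariate it was -0.11. Pmvk, phosphomevalonate kinase, averaged 91.9 ± 9.38 against 49.1 ± 6.69 TPM and Fdps, farnesyl diphosphate synthase, 72.3 ± 17.3 against 39.9 ± 1.12 TPM.

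Other adipocyte lists passed the camera threshold with less even support. Fatty acid uptake and triglyceride synthesis fell by a median of 0.43 over 18 genes (camera adjusted p = 2.33e-11, adjusted p = 0.400 with an estimated correlation). Agpat2, which acylates lysophosphatidic acid, averaged 997 ± 131 against 338 ± 126 TPM and Gpd1, a glycerol-3-phosphate dehydrogenase, 1005 ± 150 against 371 ± 174 TPM (SD, n = 3). The median was -0.23 without WT replicate 3, -0.87 without Tumor replicate 1 and -0.10 without Tumor replicate 3. Adipocyte identity fell by a median of 0.50 over 18 genes (camera adjusted p = 3.45e-09, adjusted p = 0.408 with an estimated correlation), with Acsl1 at 622 ± 198 against 343 ± 172 TPM and Nrg4 at 60.0 ± 23.3 against 33.3 ± 16.2 TPM. Its median was -0.22 without WT replicate 3, -0.90 without Tumor replicate 1, -0.76 without Tumor replicate 2 and 0.04 without Tumor replicate 3. The lipolysis list mixes genes that drive lipolysis with genes that restrain it, such as G0s2, and gives no direction of the process itself. It fell by a median of 0.28 over 19 genes (camera adjusted p = 2.32e-05, adjusted p = 0.501 with an estimated correlation). G0s2 stood at 554 ± 226 against 311 ± 214 TPM and Prkar2b at 224 ± 92.3 against 142 ± 78.4 TPM. Leaving out any of the 6 libraries moved this median by over 1.5 times, from -0.80 without Tumor replicate 1 to 0.18 without Tumor replicate 3, where the list no longer passed. Nor did it pass with the adipocyte covariate (0.066), alone or with the B and plasma cell covariate. Branched-chain amino acid breakdown fell by a median of 0.29 over 20 genes (camera adjusted p = 7.27e-08, adjusted p = 0.408 with an estimated correlation), with Mccc1 at 112 ± 18.1 against 78.2 ± 27.3 TPM and Ppm1k at 5.12 ± 1.06 against 8.41 ± 2.22 TPM. This median was -0.14 without WT replicate 3, -0.58 without Tumor replicate 1 and -0.02 without Tumor replicate 3. Across the other scalings, filters and covariates the medians ran from -1.09 to -0.12 for fatty acid uptake, -1.20 to -0.19 for adipocyte identity and -0.80 to -0.052 for branched-chain amino acids, and these 3 lists kept their calls. Adjusted over the list alone 0 members of these 4 lists passed.

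**Figure D2:**
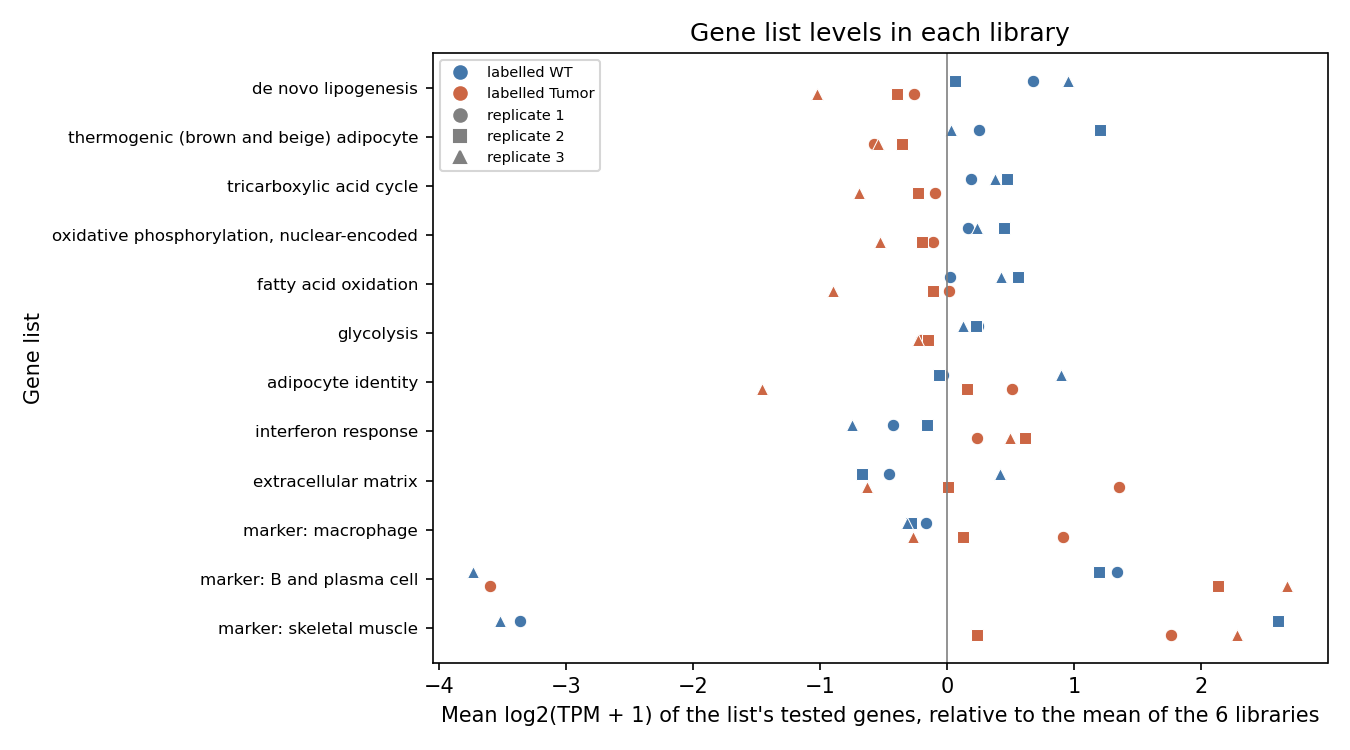
Level of 12 gene lists in each library, as the mean log2(TPM + 1) of the tested members relative to the mean of the 6 libraries, blue for libraries labelled WT and orange for those labelled Tumor. Lipogenesis, thermogenic, tricarboxylic acid cycle, oxidative phosphorylation and glycolysis levels lie lower and interferon levels higher in all 3 libraries labelled Tumor, while B and plasma cell levels divide each group, with WT replicate 3 at -3.73 and Tumor replicate 1 at -3.60.

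Interferon response genes were higher in the libraries labelled Tumor. Ifit2, an interferon-induced antiviral protein (chromosome 19, from 34550694), averaged 6.60 ± 0.752 TPM in the libraries labelled WT and 16.0 ± 3.37 TPM in those labelled Tumor (SD, n = 3), 2.43-fold higher, with a log2 difference of 1.15 (SE 0.22, limma adjusted p = 0.737). Xaf1 averaged 44.1 ± 3.73 and 74.4 ± 6.36 TPM, 1.69-fold higher. All 30 tested members had a positive difference and 20 separated the groups completely. As a list they rose by a median of 0.82 on the log2 scale (camera adjusted p = 6.28e-14, adjusted p = 0.208 with an estimated correlation, fry adjusted p = 0.0867). Adjusted over the list alone 14 members passed, all higher, and over all genes 0 did. The median was 0.61 with median-ratio factors and 0.63 with upper-quartile factors.

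Markers of skeletal muscle rose as a list, by a median of 3.31 over 16 genes (camera adjusted p = 0.00298, adjusted p = 0.731 with an estimated correlation). This followed 2 libraries labelled WT with little muscle RNA, and without WT replicate 2, which had much, the median was 5.53, whereas without WT replicate 3 it was 1.95. The list no longer passed without WT replicate 1, WT replicate 3, Tumor replicate 1 or Tumor replicate 3, with the adipocyte (2.56), macrophage (3.33) or first principal component (2.94) covariate, or in the 4 lymphoid-rich libraries (1.71). Ckm, muscle creatine kinase, averaged 180 ± 310 against 338 ± 188 TPM and Myh4 40.8 ± 70.6 against 104 ± 58.1 TPM (SD, n = 3). Neutrophil markers fell by a median of 1.07 over 11 genes (camera adjusted p = 2.88e-05, adjusted p = 0.400 with an estimated correlation), with Elane at 5.82 ± 4.03 against 2.29 ± 1.33 TPM and Retnlg at 3.56 ± 2.45 against 1.23 ± 1.21 TPM. The neutrophil median was -0.35 without WT replicate 2 and -0.68 without Tumor replicate 1, and with the macrophage covariate it was -0.39 and the list no longer passed. Mast cell and eosinophil markers fell by a median of 0.41 over 7 genes (camera adjusted p = 0.00524, adjusted p = 0.408 with an estimated correlation), with Fcer1a at 2.76 against 1.83 TPM and Mcpt4 at 58.7 against 43.5 TPM, and the median was -0.67 without Tumor replicate 1. It was -0.10 without WT replicate 2 and -0.03 without Tumor replicate 3, and in both fits, as in the fit without a low-value filter, the list no longer passed. Endothelial and lymphatic markers passed as lower at a median of -0.05 over 17 genes (camera adjusted p = 0.0250, adjusted p = 0.683 with an estimated correlation), with Pecam1 at 105 against 133 TPM and Eng at 66.7 against 53.1 TPM. Leaving out any library moved this median by over 1.5 times, from -0.31 to 0.24, and the list no longer passed without WT replicate 2, WT replicate 3 or Tumor replicate 3. It kept its call in 7 of 16 other scalings, filters, covariates and fits, and lost it among them with median-ratio factors (-0.26) and with the B and plasma cell covariate (0.094).

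Markers of other immune and stromal cells did not pass in the model with group alone. Macrophage markers had a median log2 difference of 0.64 over 22 genes (camera adjusted p = 0.15), with Lyz2 at 982 ± 251 against 1927 ± 457 TPM and Fcgr1 at 6.73 ± 0.182 against 15.4 ± 6.98 TPM (SD, n = 3). They passed as higher with median-ratio factors, with upper-quartile factors and with the B and plasma cell list as a covariate (camera adjusted p = 0.0201, 0.0278 and 0.0157), and did not with an estimated correlation (adjusted p = 0.857). Camera placed them lower without Tumor replicate 1 (median 0.13) and in the 4 lymphoid-rich libraries (median 0.092), and in neither fit did they pass. Dendritic cell and MHC class II markers stood at 0.72 (camera adjusted p = 0.441), with H2-Aa at 976 against 1831 TPM and Batf3 at 18.6 against 23.5 TPM. T and NK cell markers stood at 0.50 (camera adjusted p = 0.799), with Gzma at 7.39 against 18.2 TPM and Klrb1c at 1.85 against 5.00 TPM. For B and plasma cell markers the median was 0.89 and the mean 0.80, above the median of 0.23 of all genes. Camera compares test statistics, scaled by each gene's spread, with those of all other genes, and placed these markers lower (adjusted p = 0.666). That direction is thus not one of the log2 differences. Ighm stood at 619 against 1319 TPM and Sdc1 at 7.59 against 13.3 TPM. Unlike Cd79a, Sdc1 was highest in WT replicate 3 (10.6 TPM) and Tumor replicate 1 (21.8 TPM), each within its group. Lymph node stroma had a median of 0.62 and a mean of 0.66, again placed lower by camera (adjusted p = 0.799), with Cxcl13 at 70.6 against 162 TPM and Il33 at 11.01 against 16.3 TPM. Fibroblast and adipocyte progenitor markers stood at 0.39 (camera adjusted p = 0.845), with Dpp4 at 26.6 against 43.8 TPM and Cd55 at 65.4 against 102 TPM. They passed as higher with the B and plasma cell covariate (median 0.48) and as lower with the macrophage covariate (median -0.39). Smooth muscle and pericyte markers stood at 0.18 in the median and 0.13 in the mean, placed lower by camera (adjusted p = 0.845), with Myh11 at 8.18 against 12.8 TPM and Cspg4 at 30.8 against 15.7 TPM. Schwann cell and nerve markers stood at 0.54 (camera adjusted p = 0.534), with Mag at 1.62 against 3.20 TPM. Markers of erythroid cells and blood had a median of -0.01 and a mean of 0.05, placed lower by camera (adjusted p = 0.318), with Itga2b at 14.6 against 17.9 TPM. Mammary and other epithelial markers had a median of 0.04 and a mean of 0.14, placed lower by camera (adjusted p = 0.534), with Kcnn4 at 21.6 against 30.5 TPM and Krt19 at 2.78 against 1.82 TPM, and passed as lower without a low-value filter. With the macrophage covariate the dendritic cell (1.61), T and NK cell (2.08), B and plasma cell (3.42) and lymph node stroma (2.91) lists passed as higher. With the adipocyte covariate T and NK cells (-0.70), B and plasma cells (-0.80) and lymph node stroma (-0.63) passed as lower, and fibroblasts (0.80) and Schwann cells (0.77) as higher.

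The remaining lists concerned stress, hormones and growth. The antioxidant and Nrf2 target list fell by a median of 0.22 over 30 genes (camera adjusted p = 1.83e-07, adjusted p = 0.438 with an estimated correlation). Its lowest p-values belonged to Tkt, at 1275 ± 280 against 465 ± 111 TPM, and Taldo1, at 650 ± 22.6 against 404 ± 75.4 TPM (SD, n = 3), both enzymes of the pentose phosphate pathway. This median ran from -0.55 without Tumor replicate 1 to 0.09 without Tumor replicate 3, and moved by over 1.5 times without WT replicate 2 and WT replicate 3 too, and across the other scalings, filters and covariates it ran from -0.72 to 0.073. Glucocorticoid response genes passed as lower at a median of -0.08 over 20 genes (camera adjusted p = 0.000322, adjusted p = 0.408 with an estimated correlation), with Pdk4 at 76.5 against 29.6 TPM and Cebpd at 23.0 against 17.4 TPM, and the median ran from -0.39 without WT replicate 1 to 0.10 without WT replicate 3, moving by over 1.5 times without each library labelled Tumor as well. With the adipocyte covariate the glucocorticoid median was 0.047 and the list no longer passed (camera adjusted p = 0.0809). Methionine sulfoxide reduction and the methionine cycle passed as lower at a median of -0.04 over 21 genes (camera adjusted p = 0.00220, adjusted p = 0.408 with an estimated correlation), with Txnrd2 at 29.8 against 21.6 TPM and Cth at 8.47 against 3.40 TPM, and the median ran from -0.24 without Tumor replicate 1 to 0.14 without Tumor replicate 3, where the list no longer passed. Adipokines, peptide hormones and receptors passed as lower at -0.03 over 25 genes (camera adjusted p = 0.00212, adjusted p = 0.556 with an estimated correlation), with Angptl8 at 38.7 against 9.09 TPM and Pth1r at 30.0 against 16.7 TPM, and the median ran from -0.41 to 0.29, and the list no longer passed without WT replicate 3 or Tumor replicate 3. Circadian clock genes passed as lower (camera adjusted p = 0.0130, adjusted p = 0.408 with an estimated correlation) although their median was 0.03 and their mean -0.05, with Hlf at 3.04 against 1.97 TPM, and the list no longer passed without WT replicate 3 or Tumor replicate 3. With the adipocyte covariate the methionine (0.10), adipokine (0.25) and circadian (0.061) lists no longer passed, with the skeletal muscle covariate the adipokine (0.13) and circadian (0.033) lists, and without a low-value filter the circadian list. Leaving out any of the 6 libraries moved the medians of the methionine, adipokine and circadian lists by over 1.5 times. For these 5 lists, as for the marker lists, 0 members passed when adjusted over the list alone. Acute phase and inflammatory genes did not pass (median 0.35, mean 0.37, placed lower by camera, adjusted p = 0.666), with Cebpb at 152 against 80.1 TPM and Il1rn at 1.79 against 8.62 TPM. Autophagy and catabolic genes did not pass (median 0.06, mean 0.14, placed lower by camera, adjusted p = 0.666), with Foxo3 at 7.85 against 12.1 TPM and Sesn1 at 28.9 against 43.1 TPM. Extracellular matrix genes did not pass (median 0.44, camera adjusted p = 0.666), with Tgfbi at 74.6 against 90.7 TPM and Spp1 at 2.87 ± 2.32 against 18.9 ± 25.7 TPM, but passed as higher with the B and plasma cell covariate (median 0.68) and as lower with the macrophage covariate (median -0.48). Unfolded protein and integrated stress response genes did not pass (median 0.23, camera adjusted p = 0.845), with Pdia4 at 67.9 against 94.9 TPM and Trib3 at 4.79 against 2.70 TPM. Cell proliferation genes did not pass (median 0.42, camera adjusted p = 0.845), with Foxm1 at 2.71 against 5.65 TPM and Bub1b at 3.94 against 6.40 TPM, but passed as higher with the macrophage covariate (median 0.88) and as lower with the adipocyte covariate (median -0.045).

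**Figure D3:**
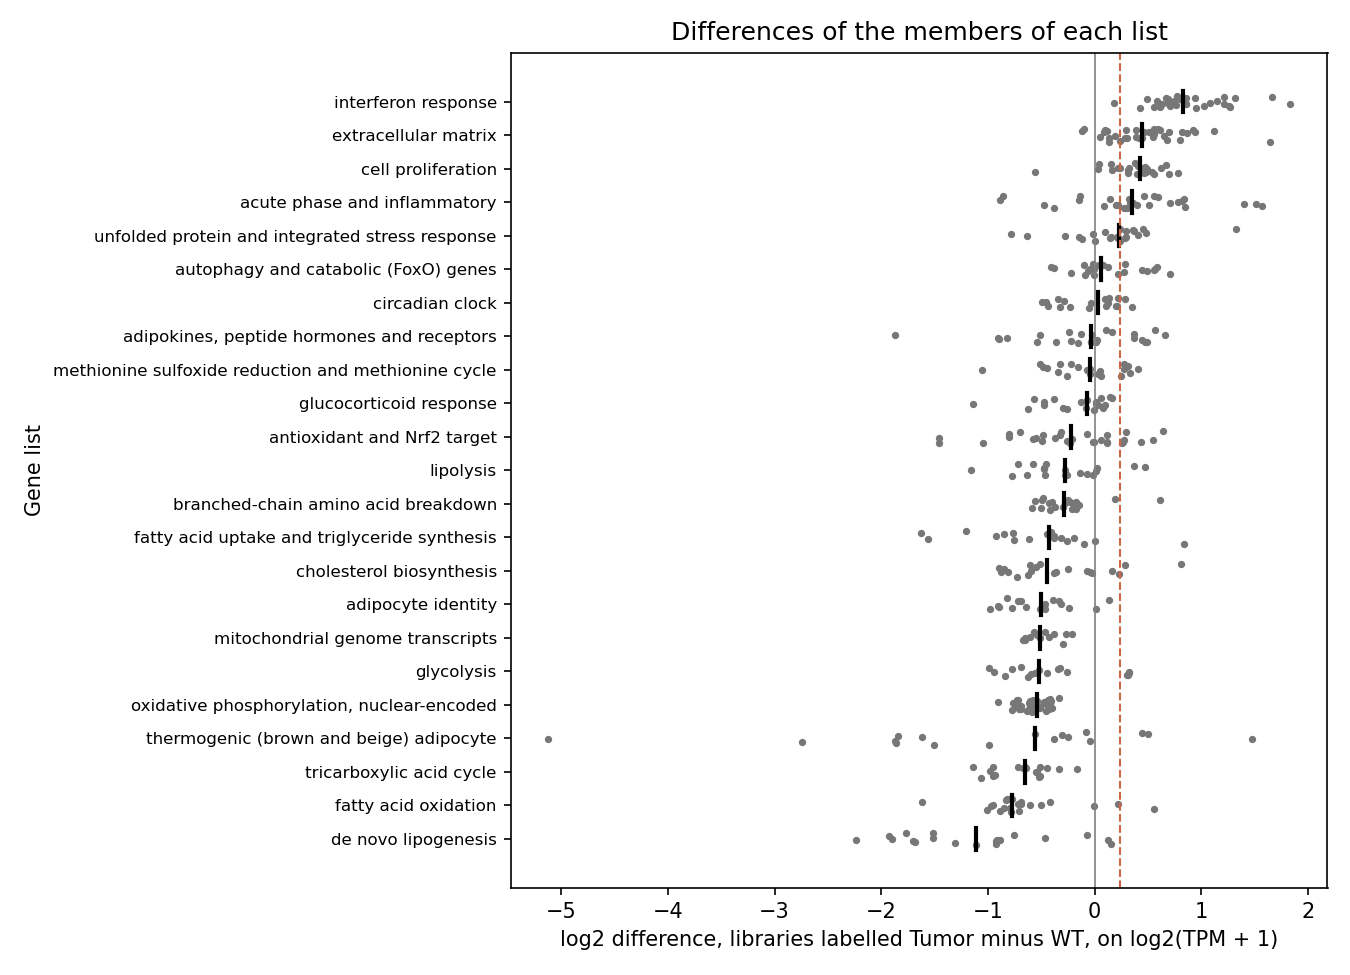
Log2 differences of the tested members of 23 lists other than cell markers, libraries labelled Tumor minus libraries labelled WT on the log2(TPM + 1) scale, 1 grey point per gene, with a black bar at the median of each list and a dashed line at 0.23, the median of all genes. All 36 oxidative phosphorylation genes lie below 0 and all 30 interferon response genes above it.

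Lists of fewer than 5 tested genes were not tested as lists. Skin and hair markers had Pmel at 1.02 against 1.99 TPM and Tyrp1 at 0.862 against 1.48 TPM. Of the pancreatic markers 1 was measured above the filter, Cela1, at 23.1 ± 9.94 against 18.7 ± 15.02 TPM (SD, n = 3). The Y-linked genes Kdm5d and Ddx3y were measured in both groups, at 7.74 against 11.3 TPM and 25.7 against 29.6 TPM.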

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

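The covariates, the fit of the 4 lymphoid-rich libraries, the pseudocounts, the fit without a trend, the estimated correlation with a covariate, and the scalings and filters as applied to TPM were tests chosen after the result was seen. DESeq2, limma-voom and the older quasi-likelihood method were planned and not run, because they need counts and the deposited values are TPM. A list was left out of each fit that had the same list as a covariate, alone, with another list or with a library left out, which removed 13 values of lists. With a library left out, 1 group holds 2 libraries. The number of fragments per library is not known, and the lowest levels rest on few fragments. Where the transcript length less 160 to 170 nt is 1 kb, 3 fragments are worth 0.115 to 0.153 TPM. The count of genes past the adjusted threshold with limma was 0 (771 at an unadjusted p below 0.05) and stayed 0 in every setting without a covariate, the block included, and with the adipocyte, macrophage or skeletal muscle covariate alone. It was 1 with the B and plasma cell covariate and 1 with the first principal component, Gm11594 in both, and 5 with the adipocyte and B and plasma cell covariates together (Gm11594, Gm28900, Gm7329, Mup16 and Gys2), all of them lower in the libraries labelled Tumor. These 5 are named because the counts are small, after their values were seen. Gm11594 is a short processed pseudogene whose TPM may rest on few fragments. Leaving out each library gave 0 genes in each fit without a covariate. With the B and plasma cell covariate it gave 0 to 27 genes, 0 to 3 higher and 0 to 24 lower, the most without Tumor replicate 2.

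The 771 genes at an unadjusted p below 0.05 became 1871 with the B and plasma cell covariate, 1655 with the adipocyte covariate, 1524 with the macrophage covariate, 1918 with the adipocyte and B and plasma cell covariates together, 2353 with the first principal component and 1231 in the 4 lymphoid-rich libraries. A minimum log2 difference of 1 left 165. The replicate block left 183, and among the lists it ended no call and added macrophages as higher (camera adjusted p = 0.0181, 0.00431 to 0.0278 in the other settings given here where they passed). Same-numbered libraries had correlations of -0.758, 0.205 and -0.843 in their deviations from the group means. The 2 lymphoid-poor libraries, WT replicate 3 and Tumor replicate 1, had 0.853, so lymphoid content can set these values. They do not show whether the numbers mark pairs. Without a covariate the count at an unadjusted p below 0.05 was 444 without WT replicate 2 and 439 without WT replicate 3. It was 1511 without Tumor replicate 1, 353 without Tumor replicate 2 and 435 without Tumor replicate 3. With the B and plasma cell covariate it was 788 without Tumor replicate 1, 1088 without WT replicate 2 and 1177 without WT replicate 3. The highest with that covariate was 2244, without Tumor replicate 2. The number of lists past the camera threshold was 22, and 1 with an estimated correlation and 1 with fry in its directional form. It was 0 with an estimated correlation and the B and plasma cell covariate together. In the other settings it stayed within 1.5 times of 22. Of the 22 lists 15 passed in each fit that left out 1 library without a covariate, and 13 of these passed in each other setting too, the 6 fits that left out a library with the B and plasma cell covariate included, apart from the estimated correlations and fry. None of the 77 named genes passed in the main fit, so keeping the side of the threshold says little of them. Over these genes and their alternatives, 2119 of 2143 values kept their direction and side of the threshold, 5 moved past the threshold and 19 turned. Over the lists 819 of 1133 did so, 121 lost the threshold, 73 gained it and 120 turned in camera's direction.

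For each change given here the cause was not tested unless stated. Of a list, turned refers to camera's direction against all other genes, and the value beside it is the list's median, which need not change sign. Fry asks whether a list moves from 0 and camera whether it moves against all other genes, whose median was 0.23. Fry turned the direction of 7 lists and left their medians in place. These were 0.35 for the acute phase list, 0.058 for autophagy, 0.89 for B and plasma cells and 0.18 for smooth muscle. For epithelium, erythroid cells and lymph node stroma they were 0.040, -0.0063 and 0.62. The medians of the acute phase list, B and plasma cells and lymph node stroma lay above 0.23. That difference between the tests alone therefore does not account for their turn. Median-ratio factors put the acute phase list, the unfolded protein list, B and plasma cells and lymph node stroma at 0.14, 0.0097, 0.68 and 0.42, and Ddx3y at -0.017. Upper-quartile factors put the same 4 lists at 0.16, 0.030, 0.70 and 0.44. Each turned in camera's direction and none passed. Without a low-value filter autophagy and smooth muscle turned at 0.058 and 0.18, and with the stricter filter T and NK cells and fibroblasts turned at 0.43 and 0.35, again without passing. The block turned the unfolded protein list at 0.23.

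With the B and plasma cell covariate cell proliferation turned at 0.17, and T and NK cells turned at -0.11 and passed, which they did not with an estimated correlation as well. With the adipocyte covariate Ighm stood at -0.041 and Cela1 at 0.034, autophagy at 0.18, dendritic cells at 0.17, endothelial cells at 0.24 and smooth muscle at 0.29, while cell proliferation at -0.045 and T and NK cells at -0.70 passed as lower. With both of these covariates autophagy stood at 0.19, the unfolded protein list at 0.22, cell proliferation at 0.13, endothelial cells at 0.24, smooth muscle at 0.27 and erythroid cells at 0.48, and T and NK cells passed at -0.33. With the first principal component autophagy stood at 0.16, cell proliferation at 0.10 and smooth muscle at 0.20, and T and NK cells passed at -0.26. With the skeletal muscle covariate Krt19 stood at 0.25, Itga2b at -0.24, the unfolded protein list at 0.22, dendritic cells at 0.27 and T and NK cells at -0.34, and cell proliferation passed as lower at -0.018. With the macrophage covariate the unfolded protein list stood at 0.12 and Schwann cells at 0.23, while the extracellular matrix at -0.48 and fibroblasts at -0.39 passed as lower and B and plasma cells at 3.42 and lymph node stroma at 2.91 as higher. In the 4 lymphoid-rich libraries the unfolded protein list stood at 0.18, cell proliferation at 0.15 and macrophages at 0.092, and B and plasma cells at 1.14 and lymph node stroma at 0.56 passed as higher.

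Other lists passed with a setting and not without it. Macrophages passed as higher with median-ratio factors (0.43), upper-quartile factors (0.45), the block (0.64), the B and plasma cell covariate (0.62), the adipocyte covariate (0.77), both covariates (0.69) and the first principal component (0.65). The extracellular matrix passed as higher with the last 4 of these (0.68, 0.89, 0.76 and 0.73), as did fibroblasts (0.48, 0.80, 0.66 and 0.55) and Schwann cells (0.51, 0.77, 0.70 and 0.56). With the macrophage covariate cell proliferation (0.88), dendritic cells (1.61) and T and NK cells (2.08) passed as higher, and dendritic cells did so in the 4 lymphoid-rich libraries (0.80). B and plasma cells passed as lower with the adipocyte covariate (-0.80), the skeletal muscle covariate (-0.12) and the first principal component (-0.20). Lymph node stroma passed as lower with the adipocyte covariate (-0.63), both covariates (0.0054) and the first principal component (-0.10), and epithelium without a low-value filter (0.040).

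Calls were lost with the adipocyte covariate for lipolysis (0.066), glucocorticoid (0.047), methionine (0.10), circadian (0.061), adipokine (0.25) and skeletal muscle (2.56) lists, and with both covariates for lipolysis (0.18), circadian (0.029), adipokine (0.22) and skeletal muscle (2.58) lists. The skeletal muscle covariate ended those of circadian (0.033), adipokine (0.13) and endothelial (0.088) lists, and the macrophage covariate those of neutrophils (-0.39) and skeletal muscle (3.33). Without a low-value filter the circadian (0.028), mast cell (-0.41) and endothelial (-0.051) lists did not pass. Endothelial cells also lost the threshold with median-ratio factors (-0.26), upper-quartile factors (-0.24), the B and plasma cell covariate (0.094), the first principal component (0.14) and in the 4 lymphoid-rich libraries (-0.027), and skeletal muscle with the first principal component (2.94) and in those 4 libraries (1.71).

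Medians also moved among lists that kept their calls. Over the settings other than leaving out a library they ran from -1.74 to -0.76 for lipogenesis, -1.20 to -0.19 for adipocyte identity, -1.09 to -0.12 for fatty acid uptake, -1.56 to -0.46 for thermogenic genes, -1.09 to -0.48 for fatty acid oxidation, -0.65 to -0.11 for cholesterol, -0.72 to 0.073 for antioxidant genes and -0.80 to -0.052 for branched-chain amino acids. The oxidative phosphorylation, mitochondrial genome, tricarboxylic acid cycle, glycolysis and interferon medians stayed within 1.5 times in these settings.

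Leaving out each library, with and without the B and plasma cell covariate, turned the sign of the following genes and camera's direction against all other genes for the following lists, given as lowest and highest values. Ighm ran from -0.0013 to 1.96, Mcpt4 from -0.82 to 0.065, Kcnn4 from -0.58 to 1.46, Krt19 from -0.81 to 0.57, Itga2b from -0.18 to 0.95, Cela1 from -1.12 to 0.077 and Ddx3y from -0.047 to 0.46. Medians, whose own sign did not turn for every list, ran from 0.13 to 0.46 for the acute phase list, -0.10 to 0.21 for autophagy, -0.14 to 0.87 for the extracellular matrix, 0.16 to 0.28 for the unfolded protein list, -0.21 to 0.81 for cell proliferation, 0.056 to 0.77 for macrophages and 0.22 to 1.37 for dendritic cells. They ran from -1.05 to 1.58 for T and NK cells, -1.02 to 2.90 for B and plasma cells (only in fits without the covariate), -0.034 to 0.75 for fibroblasts, -0.31 to 0.24 for endothelial cells, 0.078 to 0.34 for smooth muscle, 0.83 to 5.53 for skeletal muscle, -0.56 to 0.54 for epithelium, 0.42 to 0.75 for Schwann cells, -0.51 to 0.52 for erythroid cells and -0.83 to 2.35 for lymph node stroma.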

Other observations

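The tests of lymphoid content, of adipocyte share and of the Msra level, the bounds of 0.3 and -0.5 used for list medians, the splits with the B and plasma cell covariate, and the genes of the next paragraph were chosen after the result was seen.

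The following genes lie outside the lists and were picked for their values. Slc2a5, a fructose transporter, averaged 11.6 ± 1.54 TPM in the libraries labelled WT and 1.63 ± 0.527 TPM in those labelled Tumor (SD, n = 3), a log2 difference of -2.27 (SE 0.25, limma adjusted p = 0.387). Gys2, the liver-type glycogen synthase, averaged 30.4 ± 2.17 and 6.05 ± 2.11 TPM, with a log2 difference of -2.20. Both subunits of the mitochondrial pyruvate carrier were lower in all 3 libraries labelled Tumor, Mpc1 with 703 ± 38.2 and 309 ± 83.2 TPM and Mpc2 with 508 ± 31.6 and 204 ± 49.5 TPM. Among higher genes, Tlr7, an endosomal receptor for RNA, averaged 4.26 ± 0.960 and 12.8 ± 3.33 TPM. Siglec1, a lectin of macrophages, averaged 12.8 ± 3.99 and 30.5 ± 8.52 TPM, and Clec4a3, a lectin of myeloid cells, 14.8 ± 0.697 and 29.4 ± 4.40 TPM. None of these genes passed over all genes with limma on group alone, and Gys2 passed with the adipocyte and B and plasma cell covariates together. Lars2, a mitochondrial leucyl-tRNA synthetase, stood at 314, 255 and 311 TPM against 2446, 662 and 818 TPM. Lep, the leptin gene, averaged 96.7 ± 74.4 and 112 ± 82.9 TPM, a difference smaller than the spread between replicates.

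The interferon response was higher in all 3 libraries labelled Tumor, and a candidate explanation is that these libraries held more immune cells. With the B and plasma cell covariate the list median was 0.73 (SE 0.078 over 30 genes) where it was 0.82 without. With the macrophage covariate it was 0.94 (SE 0.12), and both lay above the bound of 0.3. These SEs measure the spread between genes that move together, not between libraries, and are too small. The value with the B and plasma cell covariate argues against lymphoid content as the whole cause. The macrophage list level was 0.91 in lymphoid-poor Tumor replicate 1 and 0.12 and -0.27 in Tumor replicates 2 and 3. The macrophage covariate also took the B and plasma cell median to 3.42, so it cannot decide on macrophage content, which stays open. In 1 of the 10 splits of the 6 libraries, the real one, the median was as large as 0.82, the highest other was 0.60, and 10 splits cannot give a share under 0.05. A tumour or a genotype difference stays open and was not tested, since the labels name both for the same libraries. The description identifiers of the 2 groups lie in ranges far apart, so a batch that follows the groups cannot be told apart from them either.

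The lipogenic genes may be lower because the tissue pieces held fewer adipocytes or more of another tissue. The list median of -1.11 was -0.76 (SE 0.21 over 19 genes) with the adipocyte covariate, -0.85 (SE 0.20) with the skeletal muscle covariate and -0.94 (SE 0.21) with the B and plasma cell covariate. All 3 lay below the bound of -0.5 by more than the SE, but the adipocyte value did so by little more than its SE. An SE over genes that move together is too small. The value with the B and plasma cell covariate argues against lymphoid content as the whole cause. The adipocyte and skeletal muscle covariates also took the B and plasma cell median from 0.89 to -0.80 and -0.12, where it passed as lower. These 2 covariates therefore cannot decide on adipocyte share or muscle admixture. In size, 1 of the 10 splits, the real one, reached 1.11 and the highest other 0.968, and 10 splits cannot give a share under 0.05. Adipocyte share, muscle admixture, a tumour, a genotype and a batch stay open.

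Msra was not lost in the libraries that the genotype label calls knockout. The lowest of them held 48.4% of the mean of the libraries labelled WT, which argues against a knockout that removes the transcript, while an allele that leaves the RNA in place stays open. A knockout bred from another strain could leave a flanking segment of that strain on chromosome 14. Of the tested genes within 20 Mb of Msra, 34 of 352 (9.66%) separated the groups completely, against 2080 of 13718 (15.2%) elsewhere (one-sided Fisher's exact p = 0.999). A knockout made on the same strain would leave no such segment, so this bears only on the flank. A genotype label that does not belong to these samples stays open and was not tested.

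The count of 771 genes at an unadjusted p below 0.05 was reached by 4 of the 10 splits, with 3423 as the highest other, and the count of 22 lists past the camera threshold by 5 of the 10, with 30 as the highest other. 10 splits cannot give a share under 0.05. The split with 3423 genes set WT replicate 1, Tumor replicate 2 and Tumor replicate 3 against the rest, and the split with 2881 genes set WT replicate 1, WT replicate 2 and Tumor replicate 3 against the rest. With several times the real count both point to a structure of the samples other than the groups. The other splits with the 2 lymphoid-poor libraries on 1 side gave 113 and 1356 genes. The split with 113 genes put Tumor replicate 3, with the highest B and plasma cell level (2.67), beside these 2. The first principal component followed the B and plasma cell level (Pearson correlation -0.984), so lymphoid content stays open as the structure other than the groups. With the B and plasma cell covariate the real split gave 1871 genes, the highest of the 10, and the others 174 to 1167. Leaving out 1 library with that covariate moved the real count to between 788, without Tumor replicate 1, and 2244, without Tumor replicate 2. Past the adjusted threshold the real split of all 6 libraries gave 1 gene with that covariate and the others 0 to 4. That covariate also takes up part of any split that follows lymphoid content.

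Of the genes above the filter, 4 were listed at 0 in all 3 libraries of 1 group and at 1 TPM or more in all 3 of the other, and other splits gave 0 to 15 such genes. Gm11594 was listed at 0 in the libraries labelled Tumor and stood at 8.44, 7.32 and 5.69 TPM in those labelled WT. Gm49011, Gm2581 and Tma7-ps were listed at 0 in the libraries labelled WT. All 4 are processed pseudogenes under 200 nt long, which share sequence with a parent gene, so these values are uncertain. Their lengths lie near the 160 to 170 nt taken off transcript lengths above. A single fragment can therefore be worth far more TPM here than on a long transcript, and these values may rest on few fragments.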
